A study of Homo sapiens with 6 samples.

How the data were processed

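The series holds 6 Affymetrix arrays of total RNA from human omental fibroblasts, with 1 normal and 1 co-cultured sample from each of 3 donors. Groups and donors were taken from the sample labels and the series' design text, so replicates are separate donors. The deposited values are probe set intensities on a linear scale, a MAS5 signal for each of 54675 probe sets; MAS5 is named in the submitters' processing notes, with no version. Labelling and extraction followed the manufacturer's standard protocol, per the labels. MAS5 summarises a probe set from its perfect match and mismatch probes on each array alone and scales the array; the mean signal after leaving out 2% of probe sets at each end was the same in all 6 arrays, 500.1. No detection calls, scan dates or raw probe values were used here, so no batch could be looked for. MAS5 signals of dim probe sets are noisy on the log scale, and the brightest probe sets can saturate. The number of arrays, 3 per state, limits the precision.

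Values were used as log2 of the deposited signal with no further normalization. The 62 control probe sets were left out of the tests. Gene names came from GEO's platform annotation, which listed 42898 probe sets: 41097 had 1 gene symbol, 1801 had several and 11777 had none or were not listed and are unnamed here. Of those with 1 symbol, 41043 were matched by gene identifier to a RefSeq gene table, and no symbol needed an update. Only probe sets with 1 symbol were used for genes, 19730 in all; a gene was its probe set with the highest mean log2 signal over the 6 arrays. Genes with a mean log2 signal below the median of all probe sets, a signal of 59.2, were not tested, which left 12187. XIST and genes of the Y chromosome were left out of all tables. No genome build goes with the values, so no coordinates are given.

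Co-cultured minus normal was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with donor as a fixed block because the design text compares the states within each donor. P-values were adjusted by the Benjamini-Hochberg method over the 12187 genes, and the threshold was an adjusted p of 0.05. A fold is given as a lower limit where all 3 arrays of a state lay below their own array's median signal, 61.8 to 69.7 without the control probe sets; the mean log2 of the brighter state is then set against the mean of the array medians. Same-donor samples pair by the labels. As a check, the deviations of a donor's samples from their group means correlated at 0.19, 0.17 and 0.04 across genes, against -0.17 to 0.03 for samples of different donors. Deviations cancel within a group, which pushes the latter values down, so they are no independent baseline. For donor 3, at 0.04, the check is too weak to show the pairing.

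Gene lists and single genes were fixed before the data were examined: 23 lists of pathways, matrix and secreted factors and markers of other cell types, with 546 of 581 entries on the array, and 16 single genes of fibroblast biology, among them HGF, which was too dim to test, and 1 gene whose probe set carries several symbols. The main design, the alternative settings and the rule for naming genes were fixed then too. The rule named the 12 highest and 12 lowest log2 changes among genes past the threshold that moved the same way in all pairs, all of the single genes on the array, and the 4 tested members of each list with the smallest p. Some other list members are named beside these, namely FOS, EGR1, CALB2, COL3A1, PDGFRA, DCN, LUM, CLDN3, CLDN4, ELF3, ESRP1, KRT7 and KRT18. They were chosen after their values were seen. Lists with at least 5 tested members, 21 of 23, were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 21 lists. With an estimated correlation, camera uses only the few residual degrees of freedom of the paired fit. A call lost there does not show that the list's genes vary together. RNA quality was looked at by the 3' minus 5' difference of control probe sets with an exact sign-flip test over pairs.

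The fit was tested on simulated data with 12187 genes, 3 pairs and 200 changed genes. It recovered 16% of genes with a log2 change of 1, 66% at 2, 90% at 4 and 98% at 8, with 0.735% false calls among all calls, and no unchanged list was called. The data gave 6394 calls, so the adjusted threshold was stricter in the simulation and these shares are not the recovery in the data. Noise was drawn independently for each gene, so the list result does not cover lists whose members vary together. Alternatives were no donor block, quantile, cyclic loess and median normalization, an offset of 32 before log2, no filter or one at the 75th percentile, the mean of a gene's probe sets, every probe set on its own, eBayes without a trend or robust, array weights, other thresholds, and leaving out each donor. A floor at the array median and the use of unsaturated probe sets, those with a mean log2 signal under 13, were added after the data were seen. Figures and closing tests used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.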

Results

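Fibroblasts of the omentum, the fatty apron in the abdomen to which ovarian cancer often spreads, were profiled from 3 donors in 2 states. One state was the normal omental fibroblast. In the other state, normal omental fibroblasts had been grown for 7 days together with ovarian cancer cells. The series' design text sets the states against each other within each donor, so the 6 arrays form 3 pairs, and the question is which transcripts differ between a donor's fibroblasts with and without the cancer cells. A label field calls the co-cultured cells cancer-associated fibroblasts, the name for fibroblasts of a tumour. The name of the cancer cells, the culture time of the normal fibroblasts, and whether or how fibroblasts were parted from cancer cells before RNA extraction are not given in the sources used here. Each array gave a MAS5 signal for 54675 probe sets. The median signal was 61.8 to 69.8 per array, and the 100 brightest probe sets held 5.39 to 5.61% of all signal in normal and 5.77 to 8.08% in co-cultured arrays. With 3 arrays per state, the number of arrays limits the precision.

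In co-cultured samples, 48 of 50 cell cycle genes and 17 of 28 tested chemokine and cytokine genes rose, while 17 of 19 contractile genes, 21 of 32 structural matrix genes and 13 of 16 markers of mesothelial cells, the lining cells of the omentum, fell. The shift of each of these 5 lists against the other genes passed with a preset correlation between genes and not with an estimated one (adjusted p = 0.559 with an estimated correlation). With 3 pairs the test with an estimated correlation has little power, so it does not decide. CCL5, a chemokine that attracts T cells, rose from a signal of 34.5 ± 7.92 to 2763 ± 1616 (SD, n = 3 donors). ACTA2, the smooth muscle actin of activated fibroblasts, fell from 22338 ± 2083 to 5534 ± 258 (SD, n = 3). Among the 12187 genes tested, 3192 rose and 3202 fell, together 52.5% of them, and 6389 of these 6394 moved the same way in all 3 pairs. A change of at least 2-fold was measured for 1571 of the genes that rose and 1876 of those that fell. In the same samples HMGA2 and IGF2BP3, from a list of genes typical of tumour cell lines, rose.

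Some genes went from below the median probe set of every normal array to more than 2 times the median of every co-cultured array. There were 122 of these, and 153 genes made the opposite move. For a gene below the array median in all arrays of a state, the fold is given as a lower limit, "at least N-fold", because its own signal there is near background, and such limits give the genes no order of size. Where a gene's mean signal passed 11585 in a state, its printed change is a minimum if so bright a probe set is near saturation. This applies to COL1A1, COL3A1, FN1, VIM and KRT18 in both states. It applies to LAMB3, CXCL1, CXCL8, IL1B, PLAU and TNC after co-culture and to ACTA2, TAGLN, COL4A1, MFAP5, POSTN, TIMP3, KRT19, KRT7, LUM and DCN in normal samples. TIE1, a receptor of endothelial cells, was at least 52.7-fold higher (adjusted p = 9.75e-05). LAMB3, a chain of the epithelial laminin 332, rose at least 184-fold, to a signal of 12188 ± 1142 (SD, n = 3), with an adjusted p of 0.000102. SIGLEC15, an immune receptor for sialic acids, rose at least 146-fold (adjusted p = 7.44e-05), and ESM1, a proteoglycan secreted by endothelial cells, at least 137-fold (adjusted p = 0.000102). The organic anion transporters SLCO4A1 and SLCO1B3 were at least 114-fold and 60.7-fold higher. MME, the peptidase neprilysin, rose at least 73.2-fold, MECOM, a zinc finger transcription factor, at least 38.9-fold, and IL31RA, a cytokine receptor chain, at least 26.1-fold. TMEM71, the phosphodiesterase PDE2A and the transcription factor ZIC2 completed the 12 genes named for their fitted change, at least 23.2-fold, 18.0-fold and 16.5-fold up.

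Among the genes that fell, SEL1L2 was at least 51.2-fold lower (adjusted p = 0.000175). CDH1, the epithelial cadherin that mesothelial cells also carry, fell at least 42.7-fold, from 4057 ± 3389 to 10.2 ± 10.6 (SD, n = 3, adjusted p = 0.000111). ASPN, a small matrix proteoglycan that binds collagen, fell at least 71.8-fold from 5119 ± 2442 (SD, n = 3, adjusted p = 9.75e-05). PRR9 was at least 99.6-fold lower and OLR1, a receptor for oxidised low-density lipoprotein, at least 66.7-fold. NPY, the neuropeptide Y precursor, fell by 7.85 ± 0.84 on the log2 scale (SE, adjusted p = 0.00103), and 2 of its 3 co-cultured arrays lay below the array median. SYNPO2L, a protein of muscle Z-discs, fell at least 49.0-fold, and HSD3B1, a steroid dehydrogenase, at least 21.1-fold. CLIC5, CLSTN2, ANKRD1 and the cadherin CDH6 fell at least 23.2-fold, 17.7-fold, 18.2-fold and 15.3-fold.

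Chemokines and cytokines moved upward as a group. Of 28 tested members of that list, 17 rose, 4 fell and 7 did not pass; the counts were the same 17 and 4 adjusted over the list alone. The list's median log2 change was 2.22, or 1.59 with signals under the array median raised to it, and its shift against the other genes had an adjusted p of 0.000158 (adjusted p = 0.559 with an estimated correlation). CXCL1 and CXCL8, which attract neutrophils, rose by 6.30 ± 0.34 and 5.65 ± 0.26 on the log2 scale (SE), CXCL8 to a signal of 20462 ± 3183 (SD, n = 3). The fever cytokines IL1A and IL1B rose by 5.77 ± 0.15 and 4.94 ± 0.14, with 1 normal array below the array median for IL1A. IL6 was among the brightest cytokines in both states and its change of 0.49 ± 0.21 did not pass (adjusted p = 0.0996); without donor 2 it was 0.82, with an adjusted p of 0.00504. CXCL12, a chemokine of stromal cells, fell by 1.91 ± 0.38 (adjusted p = 0.00854). In the list of NF-kB targets, 10 of 18 rose, 3 fell and 5 did not pass, unchanged in number when adjusted over the list alone (adjusted p = 0.0396; adjusted p = 0.559 with an estimated correlation). This list's call was also lost without the pairing by donor (adjusted p = 0.0789), with the filter at the 75th percentile (0.358), with the mean of a gene's probe sets (0.0970) and without donor 2 (0.0881). The survival gene BCL2A1 rose at least 76.4-fold, the prostaglandin synthase PTGS2 by 2.54 ± 0.11 and the receptor kinase IRAK2 by 3.11 ± 0.23, while the adhesion molecule VCAM1 fell by 1.98 ± 0.23.

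Growth factors went both ways: 9 of 30 rose, 17 fell and 4 did not pass, with the same numbers adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.108; 0.0266 with the filter at the 75th percentile). By fry the list passed, downward (adjusted p = 0.0331). TGFA, a ligand of the epidermal growth factor receptor, rose at least 15.3-fold, and TGFB1, the main transforming growth factor beta, rose by 1.77 ± 0.19 (SE, adjusted p = 0.00103). FGF9 fell at least 15.8-fold, the neurotrophin BDNF by 2.91 ± 0.22 and the platelet-derived growth factor PDGFD by 2.38 ± 0.20. Matrix-degrading enzymes and their inhibitors also split, with 5 of 21 up, 8 down and 8 not past, the same adjusted over the list alone; the median change was 0.04, the mean 0.29 and the test's direction down (adjusted p = 0.898). The urokinase PLAU rose by 5.47 ± 0.36, its receptor PLAUR by 2.60 ± 0.17 and the stromelysin MMP3 by 4.20 ± 0.29, and the protease inhibitor TIMP3 fell by 2.91 ± 0.18.

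Cell cycle genes were higher in co-cultured samples. Of the 50 members 48 rose and none fell, all 50 rose when adjusted over the list alone, and the median log2 change was 2.56 (adjusted p = 3.63e-14; adjusted p = 0.559 with an estimated correlation; adjusted p = 0.0571 by fry). ESPL1, the protease separase that frees sister chromatids, rose by 4.16 ± 0.26 (SE), and the mitotic kinesin KIF2C went from a signal of 452 ± 346 to 6011 ± 273 (SD, n = 3). MCM5 and MCM4, subunits of the replicative helicase, rose by 2.76 ± 0.26 and 2.28 ± 0.22. Immediate-early and growth-signal genes shifted upward (adjusted p = 0.0179; adjusted p = 0.729 with an estimated correlation): 9 of 25 rose, 1 fell and 15 did not pass, or 9 and 0 adjusted over the list alone. The members that rose included FOSL1, a partner of JUN, by 4.34 ± 0.15, the MAP kinase phosphatase DUSP5 by 3.04 ± 0.17, the signalling inhibitor SPRY4 by 2.29 ± 0.14 and MYC by 1.37 ± 0.10. FOS and EGR1, the early genes themselves, had values of -0.69 and 0.80 that did not pass (adjusted p = 0.351 and 0.292). Without donor 1 the shift of this list was lost (adjusted p = 0.446).

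Contractile genes fell nearly as a block. Of 19 tested, 17 fell, 1 rose and 1 did not pass, or 18 and 1 adjusted over the list alone, with a median log2 change of -1.99 (adjusted p = 4.94e-07; adjusted p = 0.559 with an estimated correlation). The ACTA2 change was -2.01 ± 0.12 (SE, adjusted p = 0.000198), TAGLN fell by 3.23 ± 0.13, the myosin light chain MYL9 by 4.05 ± 0.18 and calponin CNN1 by 5.03 ± 0.28. LMOD1, which nucleates actin filaments in smooth muscle, fell at least 21.9-fold. The list of structural matrix genes fell too (adjusted p = 1.62e-05; adjusted p = 0.559 with an estimated correlation): 21 of 32 fell, 2 rose and 9 did not pass, the same adjusted over the list alone. The elastic fibre gene FBLN5 fell by 5.31 ± 0.18, MFAP5 of the microfibrils by 4.36 ± 0.25, the basement membrane collagen COL4A1 by 2.11 ± 0.11 and COL8A1 by 2.40 ± 0.14. COL1A1 and FN1, the main fibrillar collagen chain and fibronectin, were among the brightest genes, COL1A1 at signals of 21664 ± 605 and 21257 ± 1314 (SD, n = 3) in normal and co-cultured samples, and had log2 differences of -0.03 ± 0.10 and -0.04 ± 0.11 (SE, adjusted p = 0.817 and 0.799). A dimmer probe set of COL1A1 gave -1.09 (adjusted p = 0.00290), the mean of its probe sets -0.71 (0.0103) and quantile normalization -0.28 (0.0416).

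Markers of activated fibroblasts divided: 11 of 20 fell, 5 rose and 4 did not pass, equal in number adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.170; 0.0432 with the mean of a gene's probe sets). Tested with fry, this list passed downward (adjusted p = 0.0454). The matrix protein TNC rose by 3.16 ± 0.23 (SE, adjusted p = 0.000354). THY1, a surface marker of fibroblasts, fell by 2.79 ± 0.18, the receptor PDGFRB by 2.42 ± 0.34 (adjusted p = 0.00250), FAP, a serine protease of tumour stroma, by 1.12 ± 0.19 (adjusted p = 0.00455), and the matrix protein POSTN by 1.07 ± 0.34 (adjusted p = 0.0419; 0.0508 to 0.0838 without the pairing by donor, the filter, the trend or donor 3). S100A4 and VIM, at 0.26 ± 0.14 and 0.32 ± 0.21, did not pass (adjusted p = 0.168 and 0.243). VIM, whose probe set is among the brightest, passed with the mean of its probe sets (0.46, adjusted p = 0.0470) and without donor 2 (0.57, adjusted p = 0.0469), and was at -0.0182 under quantile normalization. Of the 16 genes fixed singly, 14 were tested and 8 passed, also 8 adjusted over the list alone. The response genes of transforming growth factor beta showed 5 up, 6 down and 8 not past of 19, the same adjusted over the list alone; their median was 0.03, their mean -0.12 and the test's direction down (adjusted p = 0.880). COL7A1, the anchoring fibril collagen, rose by 3.56 ± 0.27 with 2 normal arrays below the array median, while the scaffold gene NEDD9 fell by 3.94 ± 0.24 and PMEPA1, an inhibitor of the pathway, by 1.63 ± 0.17.

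**Figure D1:**
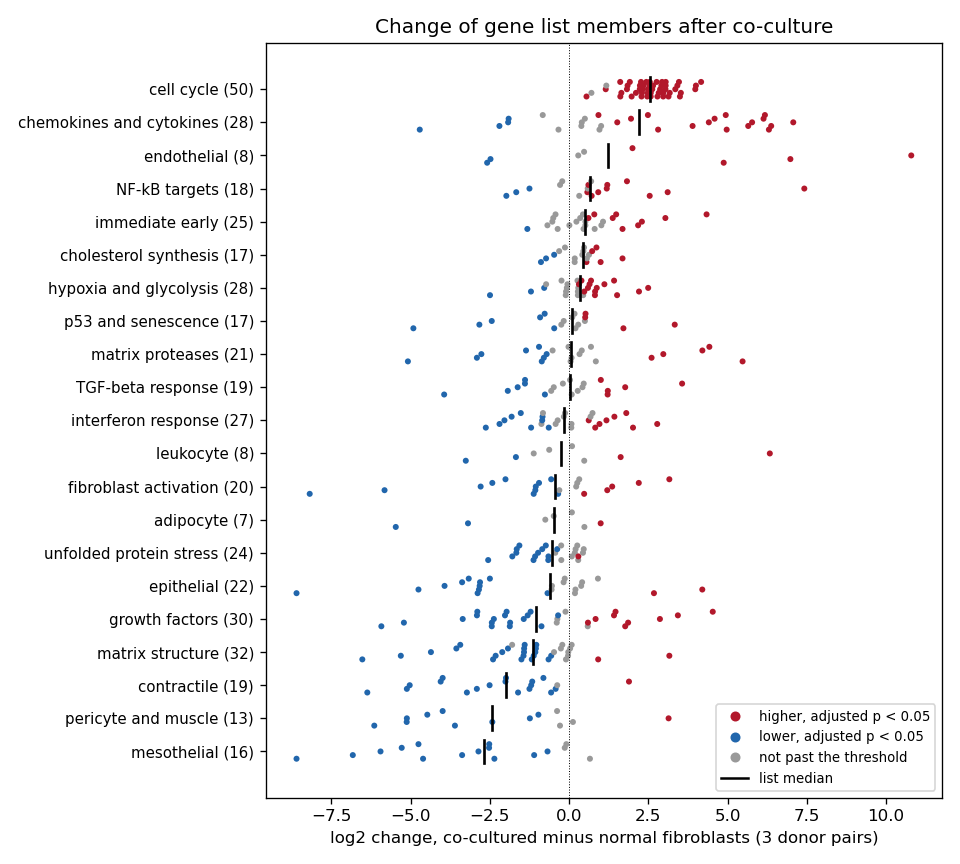
Log2 change of each tested member (points) of 21 gene lists, co-cultured minus normal fibroblasts over 3 donor pairs; red and blue points passed an adjusted p of 0.05 upward and downward, grey points did not, black bars are list medians and the number of tested members is in brackets. The cell cycle list has its median at 2.56 with every member to the right of 0, and the mesothelial list its median at -2.69.

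Hypoxia and glycolysis genes shifted upward (adjusted p = 0.0267; adjusted p = 0.729 with an estimated correlation), with 14 of 28 up, 3 down and 11 not past, or 15 and 3 adjusted over the list alone. The glycolytic genes ENO2, PFKFB4 and PFKP rose by 2.49 ± 0.21, 2.20 ± 0.15 and 1.11 ± 0.11 (SE), and ANKRD37, a target of the hypoxia-inducible factor, fell 5.65-fold. The shift of this list was lost under quantile (adjusted p = 0.0888) and loess normalization (0.0777) and without donor 3 (0.0870), and the call of PFKP with the mean of its probe sets (0.670). Genes of the unfolded protein and amino acid stress response shifted downward (adjusted p = 0.0264; adjusted p = 0.559 with an estimated correlation), 13 of 24 down, 1 up and 10 not past, the same adjusted over the list alone. Without donor 2 the call was lost (adjusted p = 0.0667). The chaperone partner DNAJB9 fell by 1.79 ± 0.15, the glutathione-degrading enzyme CHAC1 by 2.56 ± 0.24, the lipoprotein receptor VLDLR by 1.57 ± 0.13 and SEL1L, of endoplasmic reticulum degradation, by 1.12 ± 0.12. Interferon response genes were divided, 8 of 27 up, 9 down and 10 not past, the same adjusted over the list alone (adjusted p = 0.662 for the list). IFI44 rose by 2.01 ± 0.18, and GBP1, IFI27 and XAF1 fell by 2.63 ± 0.19, 2.20 ± 0.16 and 1.82 ± 0.14. The list of p53 targets and senescence genes gave 4 up, 6 down and 7 not past of 17, the same adjusted over the list alone, with a median of 0.10, a mean of -0.32 and the test's direction down (adjusted p = 0.879). With fry the p53 and senescence list passed downward (adjusted p = 0.0343). The cell cycle inhibitors CDKN2B and CDKN2A fell by 4.92 ± 0.36 and 2.83 ± 0.22, with 1 co-cultured array below the array median for CDKN2A. Cholesterol synthesis genes did not pass as a list (adjusted p = 0.278): 5 of 17 rose, 3 fell and 9 did not pass, the same adjusted over the list alone, with STARD4, a cholesterol carrier, up by 1.68 ± 0.21.

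Markers of other cell types were followed because fibroblasts from omentum can hold them and because cancer cells shared the culture. The mesothelial list fell (adjusted p = 7.21e-05; adjusted p = 0.559 with an estimated correlation), with 13 of 16 down, none up and 3 not past, the same adjusted over the list alone, and a median log2 change of -2.69, or -1.96 with dim signals raised to the array median. CALB2, or calretinin, a routine mesothelial stain, went from 3530 ± 2852 to 106 ± 21.7 (SD, n = 3), WT1 fell by 2.36 ± 0.15 (SE) and the keratin KRT19 by 3.38 ± 0.21. Epithelial markers fell on balance (adjusted p = 0.0287; adjusted p = 0.559 with an estimated correlation), 11 of 22 down, 2 up and 9 not past, or 12 and 2 adjusted over the list alone. Of the list's 40 genes 5 stand in another list as well. The call was also lost without the pairing by donor (adjusted p = 0.0666), without the filter (0.0699) and with the filter at the 75th percentile (0.273). DSP, a desmosome protein, fell by 3.17 ± 0.15, whereas PAX8, a transcription factor of the Müllerian tract, and SFN, an epithelial 14-3-3 protein, rose by 2.68 ± 0.14 and 4.20 ± 0.22. Pericyte and muscle markers fell (adjusted p = 0.00560; adjusted p = 0.559 with an estimated correlation), 9 of 13 down, 1 up and 3 not past, the same adjusted over the list alone. RGS5, a pericyte marker, fell by 5.13 ± 0.29 and the muscle filament DES by 3.99 ± 0.33 with 2 co-cultured arrays below the array median, while the proteoglycan CSPG4 rose at least 3.22-fold.

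Endothelial markers did not pass as a list (adjusted p = 0.0749; 0.0410 without a trend), with 4 of 8 up, 2 down and 2 not past, the same adjusted over the list alone. The other 10 of 18 on the array were too dim to test. By fry the endothelial list passed upward (adjusted p = 0.0133). The endothelial cadherin CDH5 rose at least 15.2-fold, ROBO4 at least 22.4-fold and PECAM1 from a signal of 70.7 ± 3.02 to 290.0 ± 77.5 (SD, n = 3), with 1 normal array below the array median. Leukocyte markers gave 2 up, 2 down and 4 not past of 8, or 2 and 3 adjusted over the list alone, and 15 of 23 were too dim to test. The median was -0.27, the mean 0.23 and the test's direction up (adjusted p = 0.954). HCLS1, a signalling protein of blood cells, rose at least 54.5-fold and the monocyte receptor CD14 fell by 3.26 ± 0.31 on the log2 scale (SE), with 2 co-cultured arrays below the array median. Adipocyte markers did not pass (adjusted p = 0.528): 1 of 7 rose, 2 fell and 4 did not pass, the same adjusted over the list alone, and 11 of 18 were too dim to test. Tested with fry, the adipocyte list passed downward (adjusted p = 0.0315). The fatty acid transporter CD36 fell by 5.47 ± 0.58 with 2 of its 3 co-cultured arrays below the array median. From the tumour cell line list 4 of 24 genes were bright enough to test, too few for a list test, and 2 rose and 2 did not pass, or 2 up and 1 down adjusted over the list alone. HMGA2, a chromatin protein of embryonic and tumour cells, went from 94.6 ± 42.0 to 5552 ± 295 (SD, n = 3), and IGF2BP3, a fetal RNA-binding protein, from 50.9 ± 33.4 to 3902 ± 89.8, with 1 and 2 normal arrays below the array median. Of 3 tested microRNA host transcripts 2 fell and 1 did not pass, the same adjusted over the list alone. MEG3 fell by 2.48 ± 0.13 (SE) and DNM3OS by 1.57 ± 0.36 (adjusted p = 0.0131), the latter with an adjusted p of 0.0857 without the pairing by donor and with 1 co-cultured array below the array median, while MIR31HG gave -0.07 ± 0.16 (adjusted p = 0.737).

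**Figure D2:**
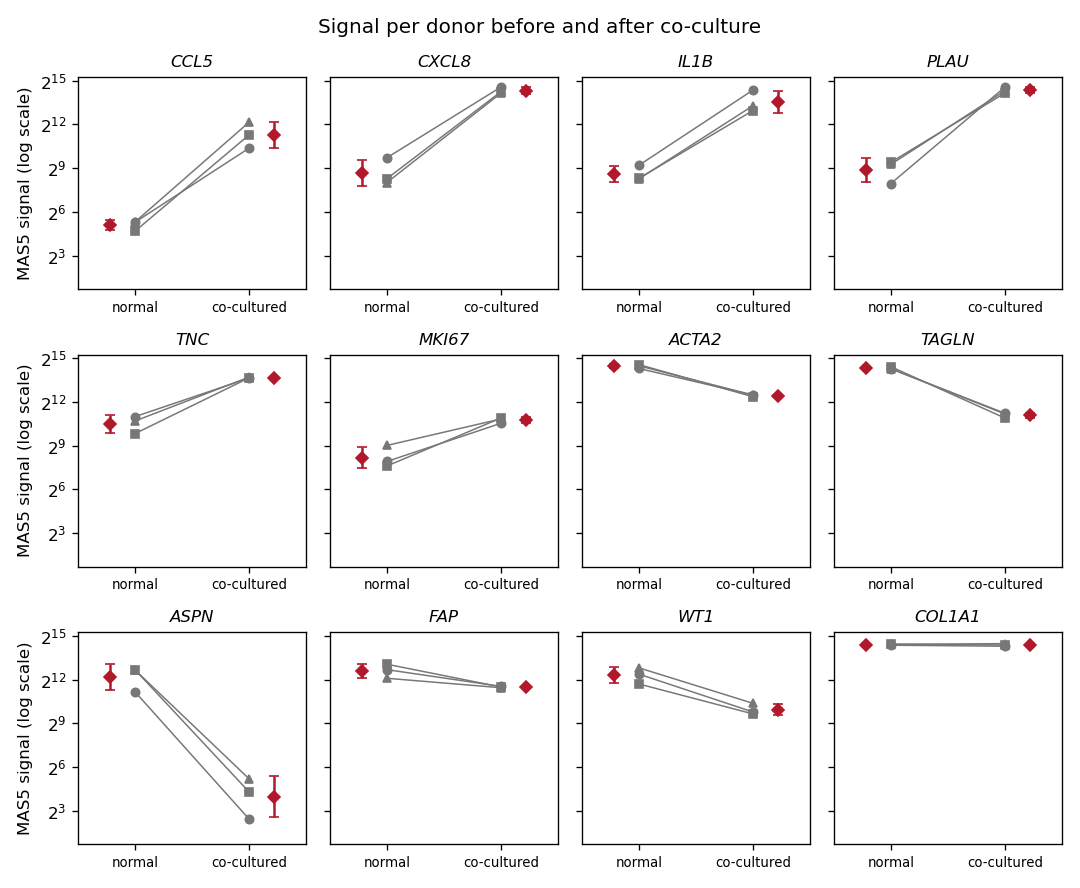
MAS5 signal (log scale) of 12 genes in normal and co-cultured fibroblasts; circles, squares and triangles are donors 1, 2 and 3 joined by a line, and red diamonds with bars are the mean and SD on the log2 scale. CCL5 and CXCL8 rise and ACTA2 and TAGLN fall in each of the 3 donors, and COL1A1 lies between 20016 and 22634 in all 6 arrays.

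The measured changes were similar in the 3 donor pairs. Across genes, the log2 changes of any 2 donors correlated with Pearson's r of 0.866 to 0.873 and Spearman's rho of 0.823 to 0.851, where genes are not independent replicates. The sign of the change was shared by all 3 pairs for 74.7% of tested genes, against 25% by chance. RNA of cancer cells in each co-cultured sample would also make the pairs alike, so the agreement does not show that the fibroblasts responded alike. Between arrays, Spearman's rho was 0.931 to 0.942 within normal and 0.911 to 0.942 within co-cultured samples. It was 0.856 to 0.885 between the states of 1 donor and 0.844 to 0.881 between the states of different donors. The 3' to 5' log2 difference of the GAPDH controls, a sign of RNA integrity, was -0.10 ± 0.02 in normal and -0.13 ± 0.01 in co-cultured samples (SD, n = 3); that of the beta actin controls was 0.31 ± 0.01 and 0.51 ± 0.11. The beta actin value was higher after co-culture in 3 of 3 pairs, with an exact two-sided sign-flip p of 0.25, the smallest that 3 pairs allow. None of the 11 list shifts past the threshold kept its call when the correlation between genes was estimated. That version rests on the few residual degrees of freedom left by 3 pairs, so losing calls was likely in advance. Growth factors, with an estimated correlation of -0.00921, below the preset 0.01, still went from an adjusted p of 0.108 to 0.559. The loss therefore neither shows that correlation between genes made the calls nor secures them. Fry, which asks whether the genes of a list move on balance in 1 direction, called 13 of 21 lists. Of the 11, fry did not call the cell cycle, hypoxia and immediate-early lists (adjusted p = 0.0571, 0.0635 and 0.0828). Beyond the 11 it called the endothelial list upward (adjusted p = 0.0133). Downward it called the adipocyte (0.0315), growth factor (0.0331), p53 and senescence (0.0343) and fibroblast activation (0.0454) lists.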

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

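The tests of between-donor spread, of epithelial markers, of probe set brightness and of the share of mesothelial markers were chosen after the results were seen; those of neighbouring genes, of donor-specific signal and of sample splits were not. Probe sets with no or several gene names, which no comparison of the report uses, also changed: 1491 of 4315 bright enough to test passed the threshold in the same limma model, 780 higher and 711 lower. The 6394 genes changed between the states compare with 0 in the highest of the other 9 splits of the 6 arrays into 3 and 3, also 0 in the 3 others that part all pairs. In all, 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Each other split mixes the states, so a large state difference widens its residual spread and makes a low count likely in advance.

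A first pattern is the set of 122 genes that no normal array showed, together with the deep falls of other genes, for which RNA of the cancer cells in the co-cultured samples is 1 explanation and a response of the fibroblasts another. Of 11 epithelial markers below the median in every normal array, 0 exceeded 2 times the median in every co-cultured array. This argues against cancer cells that carry these markers, among them CLDN3, CLDN4, ELF3 and ESRP1. Markers already seen in normal samples could not be read this way. Of the list's 22 tested members 11 fell, but KRT18 and KRT7 stayed bright after co-culture, at signals of 19195 and 8647 (log2 changes of -0.14 and -0.54). LAMB3 (at least 184-fold) and, of the epithelial list, SFN and PAX8 (4.20 and 2.68 on the log2 scale) rose. Cancer cells with few of the 11 markers stay open. An altered cancer genome carried into the samples may contribute: log2 changes of genes 20 to 40 places apart on a chromosome correlated at 0.0260. This was above the highest of 1000 shuffled orders (0.00624) and above differences between normal donors (-0.00241 to 0.00432). Differences between co-cultured donors gave 0.00295 to 0.00767, so their highest also passed the shuffled orders. These baselines cannot tell copy number from a response that neighbouring genes share. The chromosome 9 neighbours MTAP, CDKN2A and CDKN2B were at -2.72, -2.83 and -4.92 on the log2 scale, and KLHL9 nearby at -0.18. They were set side by side after their values were seen, and the cause of the falls was not tested. Open tests were the between-donor SD of the 122 genes, 0.182 against 0.150 to 0.202 in level-matched lists, and the share of donor-specific signal kept after co-culture, 0.0723 (0.00528 to 0.109 without 1 donor), beside which 94.2% of lower genes (90.5 to 99.7% without 1 donor) fell by less than dilution to that share would give and 187 of 3202 fell by more. The share was fitted over the 500 genes that varied most between normal donors. Noise in those normal signals lowers it whatever the dilution, so it cannot fix a dilution factor. No cancer cells grown alone were analysed here, any step that removed them is not given in the sources used here, and a fibroblast response stays open as untested.

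A second pattern is that the brightest probe sets of COL1A1, FN1 and COL3A1 hardly moved while some dimmer probe sets of the same genes fell. The log2 changes reached -1.09 for COL1A1, -1.04 for FN1 and -1.85 for COL3A1. Some other probe sets, nearly as bright as the brightest, did not fall, at 0.17, 0.26 and 0.18 for FN1 and 0.03 for COL3A1. Others that also lay above a mean signal of 11585 fell, at -0.71 for COL1A1 and -0.41 for COL3A1, so the split by brightness was not clean. Saturation of the brightest probe sets is a candidate explanation. Among 109 genes with a probe set above a mean signal of 11585 and another between 128 and 4096, the dimmer one changed more in 64.2%. The share was 48.9% of 597 genes whose brighter probe set lay in the middle range and whose other one lay below it. The dimmer probe sets could also detect other transcript forms, which was not tested.

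Another pattern is the fall of mesothelial markers, 81.2% of those tested (13 of 16), with none higher. Fewer mesothelial cells in the co-cultured samples, lower expression in the cells themselves and dilution by other RNA could each contribute to this count, which was known before the explanations were weighed and does not tell them apart. Dilution alone would lower fibroblast transcripts by about the list's median of -2.69 too. PDGFRA, at -0.31 ± 0.22 (log2, SE), and DCN, at -0.26 ± 0.16 on a bright probe set and -0.74 on a dimmer one, fell by less. The bright DCN probe set may be near saturation in normal samples. LUM, PDGFRB and THY1 fell by 1.40, 2.42 and 2.79. PDGFRA, DCN and LUM were picked after their values were seen, and the genes go both ways, so they do not decide. All of them fell by less than the stronger dilution that the share above would give if read as a dilution factor. Whether the cancer cells express these genes was not measured, so dilution stays open. All 16 lay above the median in every normal array, and 5 of the list's 20 genes stand in another list too.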

How the results depend on the processing

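The floor at the array median and the unsaturated probe sets were added after the data were seen. Of the 6394 calls, 6155 were shared, all in the same direction, with the 6584 of the fit without the replicate block by donor; without that pairing the list calls of epithelial (adjusted p = 0.0666) and NF-kB (0.0789) genes and the calls of POSTN, DNM3OS and LEP were lost, and no other list or named gene changed its call. Counts were 4494 to 7471 under the settings that stayed within 1.5 times, 4784 to 5465 without 1 donor, and 48.1 to 53.5% of calls were upward over the settings tested at an adjusted p of 0.05 alone. Beyond that range lay every probe set on its own (12394 called, 6219 higher and 6175 lower, of 27266 tested) and a 2-fold minimum (3447, of them 1571 higher and 1876 lower). The 75th percentile filter, within the range in total, moved by over 1.5 times in its 2088 lower genes and 4 of the fixed genes. Each of these settings tests or admits more or fewer genes. List shifts past the threshold fell to 0 with an estimated correlation, a test with little power in so few pairs. The lowest donor correlations fell to a Spearman's rho of 0.515 and a Pearson's r of 0.549 with dim genes included. The list median changed sign for matrix proteases, to -0.0118 (quantile) and -0.0185 (loess). That of the TGF-beta response went to -0.21 (quantile), -0.14 (loess), -0.34 (75th percentile) and -0.20 (mean of probe sets). The test's direction stayed down for both lists in these settings. Of single genes, the sign turned for VIM, -0.0182 (quantile), COL1A1, 0.0105, and FN1, 0.0039 (median-centred), and SC5D, 0.0204 (mean of probe sets). Without 1 donor, medians spanned -0.33 to 0.0472 for interferon, -0.0795 to 0.127 for matrix proteases, -0.0695 to 0.0589 for p53, -0.40 to 0.23 for TGF-beta and -0.76 to 0.18 for leukocyte genes, and FN1 -0.13 to 0.0139; the cause was not tested. Otherwise list results kept the sign of their median and their side of the threshold in 303 cases (12 lost and 3 gained a call). Named genes kept sign and side in 1838 (19 lost, 9 gained). Lost list calls were NF-kB targets (adjusted p up to 0.358), epithelial (up to 0.273), hypoxia (up to 0.0888), immediate-early without donor 1 (0.446) and protein stress without donor 2 (0.0667); gained were growth factors at the 75th percentile (0.0266), fibroblast activation with the mean of probe sets (0.0432) and endothelial genes without a trend (0.0410). Signals below the array median are near background and limit folds to bounds.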

Other observations

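Gene families were picked by symbol after the data were seen, and 24 of them were tested by Fisher's exact test (two-sided) against the other tested genes, in 48 tests adjusted together; the test takes genes as independent, so members that vary together make its p too small. Aldehyde dehydrogenases, which oxidise aldehydes including retinal, fell in 13 of 17 tested members and rose in none (adjusted p = 0.000210), led by the retinoic acid enzymes ALDH1A1 and ALDH1A2 at -5.29 ± 0.59 and -5.06 ± 0.19 on the log2 scale (SE, 3 pairs), the former with 2 co-cultured arrays below the array median. Insulin-like growth factor binding proteins fell in 6 of 7 (adjusted p = 0.00776), and the other one, IGFBP1, rose from a signal of 129.6 ± 158 to 573 ± 85.9 (SD, n = 3), with 2 normal arrays below the array median. Complement genes fell in 6 of 7 (adjusted p = 0.00776), with C1R at -1.99 ± 0.15, C1S at -2.03 ± 0.13 and the inhibitor CFI at -3.63 ± 0.17. Numbered cadherins fell in 6 of 8 and laminin chains in 6 of 8 (adjusted p = 0.0189 each), with CDH5 and LAMB3 as the members that rose. Genes whose symbol is SLC followed by a digit, the solute carriers and transcripts named after them such as SLC12A2-DT, fell in 95 of 225 (adjusted p = 3.47e-06) and rose in 31. The transporters with SLCO symbols were not counted among these. Zinc finger genes with ZNF symbols had the smallest p: 34 of 378 rose, fewer than among other genes (adjusted p = 1.10e-15). Of the rest, 113 fell and 231 did not pass, and the share that fell did not differ past the threshold (adjusted p = 0.238). Signal level was not matched in this test. These families had the same direction under quantile, loess and median normalization, where 12 or 13 aldehyde dehydrogenases and 88 to 92 of the SLC genes fell.

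Upward, 9 of 11 MCM genes (adjusted p = 0.00111) and 20 of 33 proteasome subunits (adjusted p = 0.000243) rose. The developmental HOXB cluster rose in 6 of 8 members, HOXB6 by 2.14 ± 0.19 and HOXB5 by 1.88 ± 0.21 (SE; adjusted p = 0.0189 for the family). Ribosomal protein genes rose in 29 of 55 and fell in none (adjusted p = 0.000243), but in 14 under quantile normalization, where 1 fell, and in 13 under cyclic loess. Among single transcription factors picked after their values were seen, SOX7, DLX1 and PAX6 rose at least 33.9-fold, 8.85-fold and 8.57-fold and FOXD1 by 4.37 ± 0.19, while GATA6 and NR2F1 fell by 2.61 ± 0.19 and 2.14 ± 0.15; the SOX and FOX families did not pass (adjusted p = 0.564 and 0.243 for higher members). On chromosome 9, MTAP, an enzyme of methionine salvage next to CDKN2A and CDKN2B, was lower on 4 of 4 probe sets, from -2.72 to -2.09, and its brightest went from a signal of 649 ± 167 to 99.9 ± 34.0 (SD, n = 3). KLHL9, a nearby gene, was at -0.18 ± 0.13 (SE, adjusted p = 0.285).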
